A study of Mus musculus with 18 samples.

How the data were processed

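ATAC-seq of mouse skeletal muscle myoblasts and myocytes was available as 4 peak lists, 1 for each group of 3 samples, as the sample labels name them. Per the submitters' processing notes, the genome build was mm9 and the tools were MACS2 and deepTools, without versions. The peak names in the lists refer to merged alignment files with a MAPQ30 tag, so peaks were called on merged replicates and not per sample. The aligner and the settings of the peak caller are not given in the sources used here. Per the labels, cells were lysed in a buffer with detergent and a Nextera library kit served for the transposition. Whether reads were shifted for the transposase is not stated. No FPKM values of the 6 RNA-seq samples were used here.

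Each deposited list has the narrowPeak layout. The fold enrichment at the summit is a ratio of the pileup to the local background, as deposited by the authors. The deposited −log10 p and −log10 q values belong to each peak, and the lowest −log10 q in any list was 2.02, which matches a q limit of 0.01. The deposited score is 10 times the −log10 q cut to a whole number and was not used. The fold, p and q values were used to describe, rank or filter peaks within a list. Folds or q values were also set side by side between lists. This was done where the same cut was applied to both lists, in counts by −log10 q, and for folds at shared regions. The genotype in the peak names was opposite to the labels in 2 of the 4 lists, both from myocytes. The lists were grouped by the labels, and the reading by peak names was added as an alternative after the data were seen.

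Depth was recovered from the lists. Fold enrichments of peaks over the genome-wide background are spaced evenly, as (pileup + 1) / (background + 1) with a whole-number pileup. The spacing of the 12 most frequent values gave the background, and the Poisson probability of a higher pileup gave the deposited −log10 p to within 0.01 for 98.5% to 99.5% of the 26.6% to 29.4% of peaks on that spacing. For named peaks, the pileup and local background that give both deposited values are stated. The spacing of the local backgrounds, from 1000 peaks per list, gave what 1 read adds. Read totals per sample are unknown, since the background also depends on the length assigned to each read. The background may also include mitochondrial reads.

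Peaks on chromosomes 1 to 19, X and Y were kept, which removed 2 or 3 mitochondrial peaks per list. Repeats and regions prone to artefact signal were not filtered out here, so the named sites and windows may include some. A peak was shared if it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1). Shares have 95% Wilson intervals (statsmodels 0.14.6), which cover counting error only. No test of the groups was possible with 1 list each, and no p-value is given. Merged regions came from all 4 lists together. Peaks were also counted by summit in fixed windows of 100 kb and ranked by the difference after scaling each list to 100000 peaks. Coordinates are mm9 and count from 1. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap, window and background steps were tested on simulated peaks (20000 for the overlap and window steps), and all 8 known quantities were recovered within 1 percent.

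The comparisons, the overlap rule and the alternatives were fixed before the data were examined, apart from those named as added. The rule for named sites took the 3 peaks without overlap with the highest fold enrichment and the 3 windows with the largest scaled difference, in each direction of each comparison. The alternatives were a q of 1e-5 or lower, a fold enrichment of at least 5, lists of equal length (88233 peaks each, by −log10 p), a reciprocal overlap of 50%, summits within 250 bp, autosomes alone, and windows of 50 and 250 kb. The gene names supplied here carry coordinates of another build (GRCm38), so peaks were not assigned to genes. For that reason the planned gene lists, promoter shares, sequence motifs and the check of the Myod1 gene were not run.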

Results

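Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse skeletal muscle cells with and without MyoD. MyoD is a transcription factor that directs cells into the skeletal muscle lineage. The 12 ATAC-seq samples formed 4 groups of 3: wild-type myoblasts, MyoD-null myoblasts, and wild-type and MyoD-null myocytes after 24 h of myogenic differentiation. Myoblasts are the proliferating precursors and myocytes the cells that have begun to differentiate. The deposited values were 1 peak list per group, called on merged reads, so every value below describes a list and carries no error between replicates. The series also holds 6 RNA-seq samples of the C2C12 myoblast line, 3 with CTCF knockdown and 3 controls, which were not analysed here.

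The genotypes of the 2 myocyte lists were recorded in opposite ways. The list deposited as wild-type myocytes holds peaks whose names read MKO-DM (MKO stands for the MyoD-null samples in their titles), and the list deposited as MyoD-null myocytes holds peaks whose names read WT-DM. The names in both myoblast lists matched their labels. The myocyte lists are therefore called here by the genotype under which they were deposited, and the counts of peaks without overlap are given under the other reading as well. The names of both myocyte lists also carry a prefix that the myoblast lists lack, so the stage of differentiation and any difference in processing cannot be told apart.

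The 4 lists differed in length. On chromosomes 1 to 19, X and Y, the myocyte list deposited as wild type held 112030 peaks over 67.6 Mb. The list deposited as MyoD-null myocytes held 88233 peaks over 51.9 Mb. Wild-type myoblasts had 98097 peaks over 52.1 Mb and MyoD-null myoblasts 101755 peaks over 51.2 Mb. The genome-wide background is a mean number of reads per base, recovered from the lists, that may include mitochondrial reads. It was 8.18 in wild-type and 8.54 in MyoD-null myoblasts. It was 5.29 in the myocytes deposited as wild type and 6.34 in those deposited as MyoD-null, so the longest list came from the shallowest background. At these backgrounds a summit needed at least 20, 21, 15 and 17 reads, respectively, to be listed, and more where the local background was higher. A region missing from a list was thus not detected at that depth, which does not show that it was closed.

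Merging all lists gave 141979 regions, of which 65178, or 45.9% (95% Wilson interval 45.6 to 46.2), were present in all 4 lists. The next most frequent class was found only in the myocytes deposited as wild type, with 23132 regions or 16.3% (16.1 to 16.5). Regions present only in the other myocyte list numbered 4849, and 4859 regions were present in both myocyte lists and in neither myoblast list. With lists of equal length, the regions found only in the myocytes deposited as wild type numbered 14126 and those only in the other myocytes 8297. Both myoblast lists without either myocyte list shared 6584 regions. Intervals here and below cover counting error only. In each comparison the longer list also held more peaks without overlap, so the net of the 2 counts follows the lengths of the lists.

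**Figure D1:**
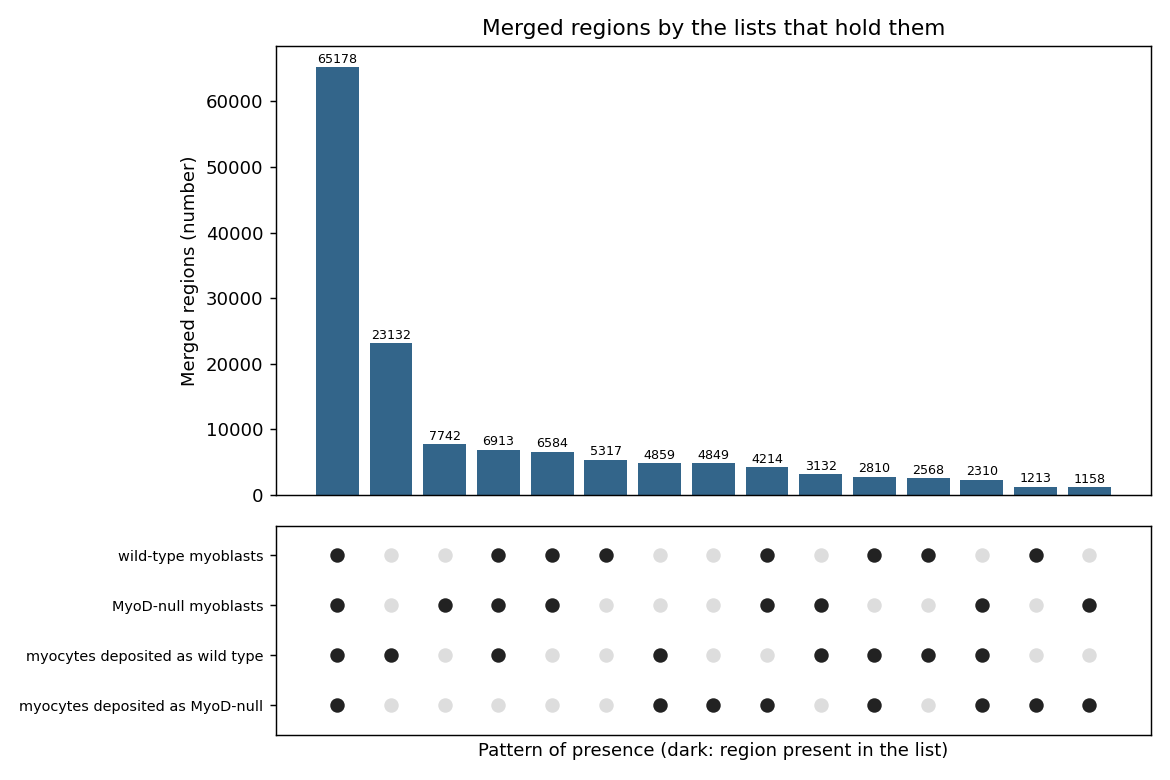
Number of merged regions (y axis) for each pattern of presence in the 4 peak lists; dark dots below each bar mark the lists that hold the region. The bar for all 4 lists stands at 65178 and the bar for the myocytes deposited as wild type alone at 23132.

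Differentiation of wild-type cells was compared first. With the deposited genotypes, 33661 of the 112030 myocyte peaks, or 30.05% (29.8 to 30.3), had no overlap in the wild-type myoblast list, and 17652 of the 98097 myoblast peaks, or 18.0% (17.8 to 18.2), had none in the myocyte list. The strongest myocyte peak without overlap in wild-type myoblasts lay at chromosome 1, 24619431 to 24620126 (mm9), with a fold enrichment of 17.3 as given by the authors. It was listed in MyoD-null myoblasts and in the other myocyte list. The second, at chromosome 12, 39600952 to 39601688, had a fold enrichment of 16.0 and was also listed in those 2 lists. The third, at chromosome 10, 16509402 to 16509996, reached 14.95 and was listed in these myocytes alone. Its summit was covered by 93 reads over a local background of 5.29. In the opposite direction, the strongest wild-type myoblast peaks absent from these myocytes were at chromosome 4, 88403049 to 88403832 (fold enrichment 9.80), chromosome 4, 88409308 to 88409782 (9.04), and chromosome 5, 105000401 to 105000970 (7.63). All 3 were listed in the other myocytes, so that none was absent from the myocytes that the peak names call wild type.

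Peaks without overlap were weaker and narrower than shared peaks of the same list. In the myocytes deposited as wild type, the median fold enrichment was 3.82 for peaks without overlap and 5.43 for shared peaks, and the median widths were 348 and 595 bp. Of the peaks without overlap, 7.70% reached the upper quartile of fold enrichment in the list. With genotypes read from the peak names, 13658 myocyte peaks were absent from wild-type myoblasts and 21922 myoblast peaks were absent from the myocytes, the reverse order. Both lists were also cut to a fold enrichment of at least 5, with the deposited genotypes. Then 30126 of 52498 myocyte peaks (57.4%) had no overlap with a myoblast peak of that fold. In the opposite direction it was 1671 of 24062 myoblast peaks (6.94%). Such peaks may be listed in the other group at a lower fold. At the 59385 regions found in all 4 lists, the median fold was 5.85 in these myocytes and 4.39 in wild-type myoblasts, so a fixed cut favours the myocytes.

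Regional differences in the wild-type comparison were ranked over windows of 100 kb after scaling to list length. The window with the largest surplus in myocytes, chromosome 5 from 140500001 to 140600000, held 16 peaks in the myocytes deposited as wild type and 3 in wild-type myoblasts. It held 3 in the myocytes that the peak names call wild type, and it was not among the first 3 windows with lists of equal length. Chromosome 1 from 183900001 to 184000000 held 20 and 7, and chromosome 2 from 113900001 to 114000000 held 13 and 2. The largest surplus in myoblasts was at chromosome 11 from 3000001 to 3100000, with 14 peaks in the myocytes and 26 in the myoblasts. Chromosome 8 from 19900001 to 20000000 held 8 and 19 peaks, and MyoD-null cells showed the same direction there, with 9 in myocytes and 23 in myoblasts. Chromosome 7 from 19500001 to 19600000 held 10 and 17.

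In MyoD-null cells, with the deposited genotypes, 14261 of 88233 myocyte peaks, or 16.2% (15.9 to 16.4), were absent from the myoblast list. Of the 101755 MyoD-null myoblast peaks, 25127 or 24.7% (24.4 to 24.96) were absent from the myocyte list. The strongest peak of these myocytes absent from MyoD-null myoblasts was at chromosome 6, 51917429 to 51918127, with a fold enrichment of 11.2, and it was also listed in the other myocytes. The next were at chromosome 4, 88409317 to 88409884 (10.9), and chromosome 5, 105000361 to 105001102 (10.6), both of which were listed in wild-type myoblasts. The strongest myoblast peaks absent from these myocytes were at chromosome 7, 70947561 to 70948134 (8.49), chromosome Y, 1790385 to 1790902 (8.28), and chromosome 14, 80329174 to 80329619 (7.96). All 3 were also listed in wild-type myoblasts. The chromosome 14 site was listed in the other myocytes too, which the peak names call MyoD-null.

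The windows with the largest scaled surplus in the myocytes deposited as MyoD-null were on chromosome 3 from 54900001 to 55000000, with 17 peaks against 10 in the myoblasts (not among the first 3 under the other window sizes or with lists of equal length), chromosome 6 from 115900001 to 116000000, with 23 against 17, and chromosome 8 from 123000001 to 123100000, with 22 against 16. After the window on chromosome 8 from 19900001, the largest surpluses in myoblasts were on chromosome 12 from 114500001 to 114600000 and chromosome 4 from 125500001 to 125600000, each with 2 peaks against 12. With genotypes read from the peak names, MyoD-null myocytes had 33628 peaks absent from the myoblasts and MyoD-null myoblasts had 20189 absent from the myocytes. With both lists cut to a fold enrichment of at least 5 and with the deposited genotypes, the myocyte list was the longer one. Then 13092 of 35104 myocyte peaks had no overlap with a myoblast peak of that fold. In the opposite direction it was 2663 of 24737 myoblast peaks. Such peaks may be listed in the other group at a lower fold. At the 59385 regions found in all 4 lists, the median fold was 5.05 in these myocytes and 4.40 in MyoD-null myoblasts.

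**Figure D2:**
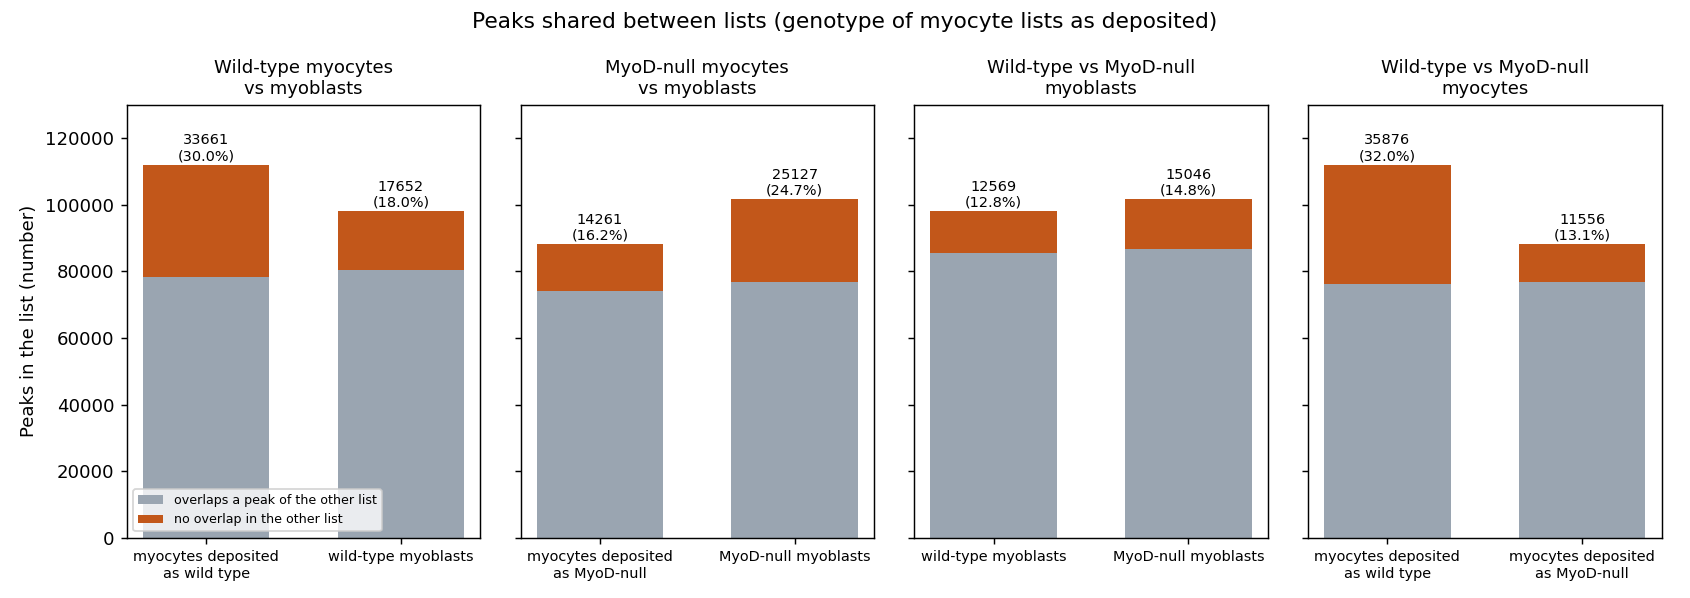
Number of peaks (y axis) in each list of the 4 comparisons, divided into peaks that overlap the other list by at least 1 bp (grey) and peaks that do not (orange, with number and share above the bar). Peaks without overlap range from 11556 (13.1%) in the myocytes deposited as MyoD-null to 35876 (32.0%) in the myocytes deposited as wild type.

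For loss of MyoD in myoblasts, labels and peak names gave the same genotypes. Of the wild-type peaks, 12569 or 12.8% (12.6 to 13.02) were absent from MyoD-null myoblasts, and 15046 MyoD-null peaks or 14.8% (14.6 to 15.01) were absent from wild-type myoblasts. Only 0.199% of the former and 0.0532% of the latter reached the upper quartile of fold enrichment in their list. The strongest wild-type peaks absent from MyoD-null myoblasts were the same 3 sites on chromosomes 4 and 5 named for wild-type differentiation, with summits of 124, 82 and 69 reads. The strongest MyoD-null peaks absent from wild-type myoblasts were at chromosome 5, 98537535 to 98537854 (fold enrichment 5.34), chromosome Y, 2795427 to 2795716 (5.24), and chromosome 15, 37115858 to 37116323 (5.15).

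The 2 chromosome 4 sites flanked another wild-type peak at 88406356 to 88406690, with a fold enrichment of 6.55. This peak and the flanking peak from 88367690 were chosen after their values were seen. All 3 were listed in the myocytes deposited as MyoD-null, with folds of 9.04, 5.80 and 10.9, and none was listed in the myocytes deposited as wild type. The neighbouring peak at 88367690 to 88368702 was listed in all 4 groups, with folds of 7.76 in wild-type and 8.39 in MyoD-null myoblasts. By windows, the largest scaled surplus in wild-type myoblasts was at chromosome 4 from 127900001 to 128000000, with 6 peaks against 0 in MyoD-null myoblasts. It was not among the first 3 with windows of 50 or 250 kb or with lists of equal length. Next came chromosome 1 from 74000001 to 74100000, with 20 against 15, and chromosome 9 from 9100001 to 9200000, with 18 against 13. MyoD-null myoblasts had more peaks at chromosome 5 from 140500001 to 140600000, with 9 against 3 (not among the first 3 with windows of 250 kb or lists of equal length), at chromosome 11 from 51100001 to 51200000, with 10 against 4, and at chromosome 6 from 34900001 to 35000000, with 10 against 4.

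**Figure D3:**
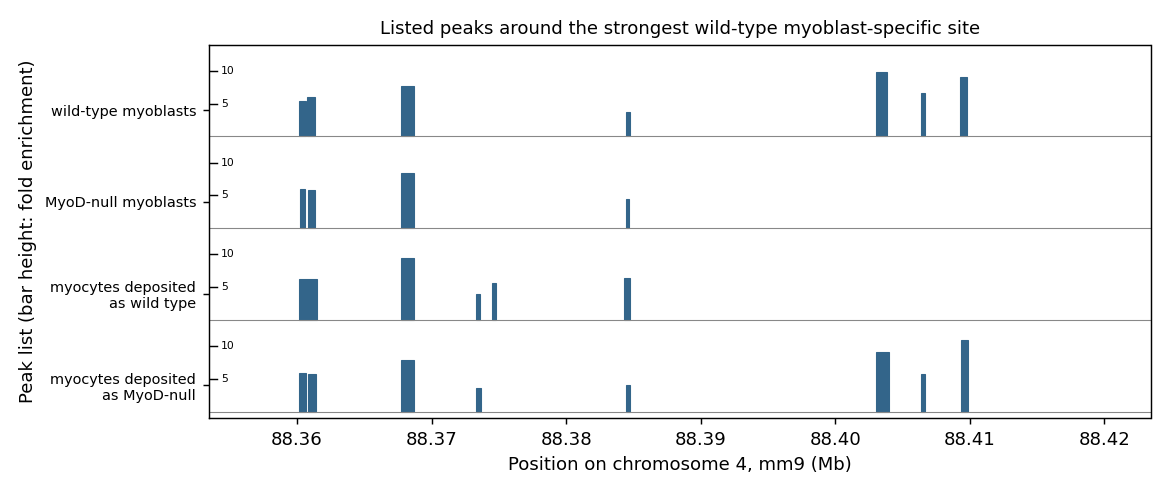
Position on chromosome 4 of mm9 in Mb (x axis) of the peaks listed in each group; each bar spans a peak and its height is the authors' fold enrichment, on the same scale in every list. Peaks at 88403049, 88406356 and 88409308 in wild-type myoblasts have counterparts in the myocytes deposited as MyoD-null and none in the other 2 lists.

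Between the 2 myocyte lists, 35876 peaks of the list deposited as wild type, or 32.0% (31.8 to 32.3), were absent from the list deposited as MyoD-null. The reverse held for 11556 peaks or 13.1% (12.9 to 13.3). The strongest peak of the first kind was at chromosome 16, 46251674 to 46252302 (fold enrichment 17.3). It was listed also in wild-type myoblasts and not in MyoD-null myoblasts. Next came chromosome 16, 86015474 to 86016265 (14.96, listed also in both myoblast groups), and the chromosome 10 site from 16509402. The strongest of the second kind were the sites on chromosome 4 from 88409317 and chromosome 5 from 105000361, and a site at chromosome 9, 104884307 to 104884918 (10.4), which was listed in these myocytes alone. The windows with the largest surplus in the myocytes deposited as wild type were on chromosome 5 from 140500001, with 16 peaks against 3, and on chromosome 17 from 30600001 to 30700000, with 17 against 4, and from 5200001 to 5300000, with 23 against 9. In the myocytes deposited as MyoD-null the surplus was largest on chromosome 8 from 35800001 to 35900000, with 15 against 6, then on chromosome 11 from 3000001, with 20 against 14, and on chromosome 5 from 115900001 to 116000000, with 23 against 19. Between the myocyte lists, the chromosome 5 window from 140500001 was not among the first 3 with windows of 50 or 250 kb or with lists of equal length. Read by peak names, the counts belong to the opposite genotypes. With lists of equal length, which hold both counts close together, they were 20447 (23.2%) and 19676 (22.3%).

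Peaks absent from myoblasts were then followed into the other genotype. Of the 33661 peaks in the myocytes deposited as wild type that were absent from wild-type myoblasts, 7364 or 21.9% (21.4 to 22.3) overlapped a peak of the other myocyte list, and 5527 or 16.4% (16.0 to 16.8) overlapped a MyoD-null myoblast peak. The 78369 peaks that were present in wild-type myoblasts overlapped the other myocyte list in 87.8% (87.5 to 88.0) and the MyoD-null myoblast list in 93.0% of cases. Those peaks were also stronger, with a median fold of 5.43 against 3.82. Divided by the MyoD-null myoblast list instead, the same myocyte list overlapped the other myocytes in 23.4% (absent) and 87.1% (present). The contrast was thus not particular to the genotype of the myoblasts. Under the mirrored question, 57.3% (56.5 to 58.1) of the 14261 peaks in the myocytes deposited as MyoD-null that were absent from MyoD-null myoblasts overlapped the longer myocyte list. With genotypes read from the peak names, 55.9% (55.04 to 56.7) of the 13658 peaks gained by wild-type myocytes were listed in MyoD-null myocytes. The 21.9% rose to 29.2% with lists of equal length.

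Peaks on chromosome X made up 1.69% (1.61 to 1.77) of the wild-type and 1.51% (1.44 to 1.59) of the MyoD-null myoblast list. Their share was 2.02% (1.94 to 2.10) in the myocytes deposited as wild type and 1.87% (1.78 to 1.96) in those deposited as MyoD-null. Of the 2260 X peaks in the myocytes deposited as wild type, 37.2% (35.2 to 39.2) were absent from wild-type myoblasts, above the 30.05% of that whole list. Of the 1646 X peaks in the other myocytes, 22.4% (20.5 to 24.5) were absent from MyoD-null myoblasts, above the 16.2% of that list. In the opposite direction X and Y together lay below their lists. Without them, 18.08% of wild-type myoblast peaks were absent from the myocytes deposited as wild type, against 17.99% with them. For MyoD-null myoblast peaks absent from the myocytes deposited as MyoD-null it was 24.84%, against 24.69%. The cause was not tested. For genotypes read from the peak names, the shares of X peaks without overlap were not computed. Chromosome Y held 12 to 25 peaks in each list.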

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

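The test of exchanged myoblast lists, the tests of sequencing depth, the reading of genotypes from peak names and the counts by peak strength were chosen after the values were seen; the others were set beforehand.

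The number of listed peaks changed in opposite directions on differentiation in the 2 genotypes as deposited. Peaks only in myocytes minus peaks only in myoblasts came to 16009 for wild type and -10866 for MyoD-null cells, close to the differences in list length of 13933 and -13522. Genotypes read from the peak names gave -8264 and 13439. With both lists cut to a fold enrichment of at least 5, the deposited genotypes gave 28455 and 10429 (differences in length 28436 and 10367). At regions in all 4 lists, median folds were 5.85 (deposited as wild type) and 5.05 (deposited as MyoD-null) in myocytes. They were 4.39 and 4.40 in wild-type and MyoD-null myoblasts. A fixed cut thus favours myocytes in both genotypes and cannot decide on the contrast. Lists of equal length gave 1752 and 2048, where equal lengths hold the net near 0. With 1 list per group the difference between the genotypes was not tested.

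Among the windows of 100 kb named above for the 2 differentiation comparisons, 3 differed between myocytes and myoblasts with opposite signs in the 2 genotypes as deposited. The values are scaled numbers of peaks (per 100000 peaks of the list), and none of these differences was tested. The windows had been picked for a large difference, and opposite signs were not counted genome-wide. Over all 18967 windows, unscaled counts were higher in myocytes in 9375 for wild type and lower in 9555 for MyoD-null cells. At chromosome 5 from 140500001 the difference was 11.22 in wild type (16 against 3 peaks) and -5.44 in MyoD-null cells (3 against 9). At chromosome 2 from 113900001 it was 9.57 (13 against 2) and -0.38 (4 against 5). At chromosome 6 from 115900001 it was -0.37 (19 against 17) and 9.36 (23 against 17), where the negative sign comes from the scaling alone. With genotypes read from the peak names the signs were not opposite: 0.34 (3 against 3 peaks, a sign from the scaling alone) and 5.44 (16 against 9) on chromosome 5, 2.49 (4 against 2) and 6.69 (13 against 5) on chromosome 2, and 8.74 (23 against 17) and 0.25 (19 against 17) on chromosome 6.

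The genotypes of the myocyte lists are recorded in opposite ways. Wild-type myoblast peaks absent from MyoD-null myoblasts overlapped the myocytes deposited as wild type in 47.4% and those deposited as MyoD-null in 35.5%, against 40.2% and 26.0% for MyoD-null myoblast peaks absent from wild type. The ratio of these ratios was 0.864 (95% interval 0.831 to 0.897, from 1000 draws of 10 Mb blocks), and 0.835 to 0.954 over the 8 settings, with the whole interval below 1 in 7 of them. This argues against exchanged peak names with correct file names, and is consistent with exchanged file names. Of the wild-type peaks of this kind, those only in the myocytes deposited as wild type against those only in the other myocytes numbered 1628 and 837 at a −log10 q of at least 5, 94 and 82 at 10, and 2 and 13 at 15, while the MyoD-null peaks numbered 2423 and 899, 205 and 93, and 11 and 1. Exchanged myoblast lists would give the same ratio of 0.864, so the 2 exchanges cannot be told apart by it. Peak names and labels agreed in both myoblast lists, however. An exchange of these lists would leave the conflict in the myocyte lists unexplained. A change of these sites with differentiation stays open and untested. The chromosome 16 site from 46251674, picked for its fold in the myocytes deposited as wild type, followed the deposited genotypes. It was listed in wild-type myoblasts and in neither list deposited as MyoD-null. Its strength in wild-type myoblasts was not examined. It was not among the 12 wild-type myoblast peaks absent from MyoD-null myoblasts with a −log10 q of at least 20. Of those, 8 were listed only in the myocytes deposited as MyoD-null, 0 only in those deposited as wild type, and 4 in both.

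The list of myocytes deposited as wild type was the longest, and it held 2.36 times as many peaks absent from its myoblasts as the other myocyte list. Greater depth in all reads together is argued against by its background pileup of 5.29, below the 6.34 of the other myocytes. The backgrounds are comparable if the local window was the same, since 1 read added 0.02 to the local background in all 4 lists. All 4 lists held mitochondrial peaks, so the background may count mitochondrial reads. Greater depth outside these reads stays open. Higher enrichment across the whole library is consistent with the median fold at 59385 regions found in all 4 lists, which was 1.16 times that of the other myocytes. List length at the authors' threshold stays open: with lists of equal length the ratio of 2.36 was 1.20, between the bounds set for either outcome. An effect of genotype also stays open, in a direction that depends on which record of genotype is right.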

How the results depend on the processing

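Values are given as peaks only in the first list and only in the second, for wild-type myocytes against myoblasts, MyoD-null myocytes against myoblasts, wild-type against MyoD-null myoblasts, and wild-type against MyoD-null myocytes. Among alternative values of these counts, of the regions in all 4 lists or in the myocytes deposited as wild type alone, and of the share of gained peaks found in the other myocytes, 49 stayed within 1.5 times the reported count or within the interval of the share, and 25 did not. Among net differences, leading windows, chromosome X shares and the share of kept peaks, 37 stayed, 24 moved and 6 turned in direction, where a leading window counted as staying if it was among the first 3. Over 24 cases of a leading window under an alternative, it stayed first in 6 and among the first 3 in 12. Genotypes read from the peak names, chosen after seeing the data, gave 13658 peaks only in wild-type myocytes (net -8264, direction turned), 33628 only in MyoD-null myocytes (net 13439, turned), and 11556 and 35876 between the myocytes (net -24320, turned). Lists of equal length gave 22147 peaks only in wild-type myocytes, 16432 only in MyoD-null myoblasts (net 2048, turned), a net of 818 between the myoblasts (turned), 20447 and 19676 between the myocytes, and 14126 regions in the myocytes deposited as wild type alone; equal lengths force both counts of a comparison close together, so the turned signs say nothing about direction. A fold enrichment of at least 5 in both lists gave 1671 peaks only in wild-type myoblasts and 2663 only in MyoD-null myoblasts (net 10429, turned). It gave 3182 and 3838 between the myoblasts, and 22296 and 4926 between the myocytes. Peaks counted in this way may be listed in the other group below the cut. Folds were higher in both myocyte lists at regions in all 4 lists, so this turned sign says nothing about direction. A q of 1e-5 or lower against the full other list gave 7261 peaks only in wild-type myoblasts relative to MyoD-null. Reciprocal overlap of 50% gave 29531 peaks only in wild-type myoblasts relative to myocytes and 20171 only in the myocytes deposited as MyoD-null. The share of 21.9% of gained peaks found in the other myocytes became 22.7% at a q of 1e-5, 23.1% against the full list, 31.0% at a fold of 5, 29.2% at equal length, 23.7% at reciprocal overlap, 23.6% by summits and 55.9% by peak names. Beyond the list length named above, the cause of these changes was not tested. No paired analysis was possible because the replicates were merged before peaks were called; for the same reason no replicate could be left out. The alternatives for gene lists, promoters, motifs and the RNA-seq comparison were not run. At the genome-wide background a summit of fewer than 15 to 21 reads goes unlisted, and a higher local background raises this limit.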

Other observations

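Among wild-type myoblast peaks absent from MyoD-null myoblasts, 12 had a −log10 q of at least 20, and no MyoD-null peak of this kind did. At a −log10 q of at least 15 the counts were 44 and 42, so this contrast depended on the cut. The 12 peaks were singled out after their values were seen. At a −log10 q of at least 10, more wild-type peaks were listed only in the myocytes deposited as wild type (94) than only in the other myocytes (82). For MyoD-null peaks of this kind the numbers were 205 and 93. The list deposited as wild type was also the longer one, which favours the first number in both cases. Of the 12, 8 were listed in the myocytes deposited as MyoD-null and not in those deposited as wild type, 4 in both and 0 only in the latter. The 8 included the 3 neighbouring sites on chromosome 4 from 88403049, and others at chromosome 5, 105000401 to 105000970, chromosome 11, 31069149 to 31070359, chromosome 7, 46910566 to 46911061, and chromosome 4, 127966835 to 127967191 and 132527570 to 132528046.

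Peaks were wider in both myocyte lists, with medians of 498 bp (deposited as wild type) and 483 bp (deposited as MyoD-null) against 421 and 398 bp in wild-type and MyoD-null myoblasts. At the 59385 regions found in all 4 lists, the median widths were 623 and 553 bp in myocytes and 516 and 496 bp in myoblasts, ratios of 1.21 and 1.11. Separate processing of myoblast and myocyte lists may contribute, and the smaller ratio of 1.11 met the bound set for it beforehand. With genotypes read from the peak names, chosen after the values were seen, the ratios were 1.26 and 1.07, the smaller of which did not meet it. Differentiation itself cannot be told apart from it, since the names of both myocyte lists carry a prefix that the myoblast names lack.

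Regional clustering of gained peaks was tested as a hypothesis. In the myocytes deposited as wild type, 1817 windows of 100 kb held 5 or more peaks absent from wild-type myoblasts, against a median of 1713 (range 1620 to 1795) over 1000 reassignments of the same number of peaks within each chromosome. The observed number lay above every reassignment, by a small margin, so gained peaks may be slightly clustered. These windows held 32.4% of the gained peaks. That share was not computed for the reassignments, in which nearly as many such windows arose, so it does not measure clustering. The pairings read from the peak names were not examined. In the myocytes deposited as MyoD-null, 167 windows were found, within the range of 105 to 175, and the difference between the 2 lists was not tested.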
